A study of Mus musculus with 3 samples.

How the data were processed

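Genomic DNA of mouse BCR-ABL1 leukaemia cells was hybridized to 3 Agilent 244A mouse genome arrays, per the labels. Each array carried AID WT DNA in Cy5 (red) and AID KO DNA in Cy3 (green), with no array in which the dyes were exchanged. The labels call the WT sources WT MIG1, WT MIG2 and WT MIG3 and the KO source KO MIG, and do not explain the term MIG. Images were read with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited log10 values are the log10 of the red over the green processed signal, per the file headers. The deposited processed intensity values were background-subtracted, detrended and dye-normalized with a linear factor per channel, per the file headers. The deposited mean and background intensity values are spot brightness and median local background. Probe positions are on the genome build mm8, per the labels, and are given as the files give them.

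The log10 ratios were multiplied to log2 and centred on the median of each array, without loess, and spots of the same probe were averaged (1400 probes were spotted more than once, with an SD of 0.105, 0.110 and 0.113 between their spots on the 3 arrays). This left 235402 probes, 233214 with a position and 220668 on autosomes. Signals not well above background numbered 353, 335 and 369 in the WT channel and 327, 373 and 360 in the KO channel. The spread of differences between neighbouring probes, given by the scanner software, was 0.236, 0.220 and 0.224. Sex chromosomes were kept out of the gene test because the labels give no sex.

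The arrays gave 25736 gene names. Against the RefSeq table of assembly GRCm38.p6, used for names only, 12862 were current, 3338 were updated by accession, 201 by synonym and 9335 kept as in the files, many of them cDNA names. Another 93 names lay on several chromosomes and were left out, Tcf3 among them. Of the list members, Vpreb1, Vpreb2, Igll1, Rhoh, Cdkn2b, Cdkn1b, Bcr, Mdc1 and Cd8a had no value either.

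The KO DNA was the common reference and the only control, so the ratio against 0 was the test of WT against KO. It was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the mean of the probes of each of 24636 genes and on 220624 single probes. No covariate, pairing or block was used. If the WT DNAs were not independent, the p-values measure technical spread. On simulated data for 24636 genes with 50 changed at each size, the test recovered 14 at a log2 change of 0.25, 33 at 0.5, 46 at 1 and 50 at 2, with 2 false calls. The simulated noise was drawn separately for each array. It therefore does not measure false calls from the shared KO DNA or from the dyes. Lists were tested with limma camera with the correlation preset at 0.01 and estimated, adjusted over 9 lists. These included B-lymphoid genes, AID off-targets, tumour suppressors, oncogenes and cell cycle genes, DNA repair and mutation genes, genes of T and myeloid lineages, olfactory and vomeronasal receptors and strain-variable families; 1 further list is not reported here. Lists for the receptor loci and for homologues of the construct matched at most 1 measured gene each and were not tested.

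Segments were found on each array by penalised least squares (penalty 10 times the squared noise times the natural log of the number of probes, at least 5 probes), after single-probe outliers were shrunk, and called at a mean of 0.3 or more from the array median. Segmentation of single arrays, not of their differences, was tested on simulated data. A change of 2 log2 units was recovered in 114 of 114 cases with 5 probes, and a change of 0.5 in 76 of 114 with 50 probes and in 0 of 114 with 20, with 1 false segment in 3 arrays. Shared segments were runs of at least 5 probes called alike on all 3 arrays, set against 10000 circular shifts. Segments of 1 WT sample were sought in each array minus the mean of the others. The signal of each DNA by chromosome or window was the log2 of the processed signal. Correlations between arrays were set against simulated WT samples without change.

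Named were Pax5, Cdkn2a, Ebf1, Ikzf1, Myc, Abl1 and Bcr; up to 3 genes of the 5 most gained and 5 most lost segments of each array and of the shared ones; genes of segments of 1 WT sample; up to 4 members of each list that passed the test or lay in a called segment, those with the largest change; and the 10 genes highest and 10 lowest in WT. Another gene fixed in advance is not reported here. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The receptor loci were bounded by probes whose cDNA descriptions name the receptor, a choice made after the gene names turned out to match few of them. Single channel signals by region and the distal parts of chromosomes 5 and 18 were also chosen after seeing the data.

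Alternatives were normexp background correction (offset 50), within-array loess, centring on the mode, probes well above background in both channels, leaving out each array, the median of a gene's probes, genes with at least 3 probes, a penalty of 20, segments of at least 10 probes and a threshold of 0.5. Plain background subtraction and shared segments without chromosomes 10 and 18 were added after seeing the data. The deposited series table holds a score of unstated scale for 24427 numbered entries, with no unit given by the authors. For the 24402 numbers that matched a feature number its correlation with the log ratio was between -0.0063 and -0.0024, so it was not used further. Segmentation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and tables were read in R with the data.table package, version 1.17.8.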

Results

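Copy number was compared between mouse BCR-ABL1 leukaemia cells that the labels call AID WT and AID KO. Comparative genomic hybridization was done on 3 arrays, each with an AID WT DNA under its own name (here WT1, WT2 and WT3, Cy5) against AID KO DNA (Cy3) that carried the same name on every array. Each array had 238202 features that were not controls. The median spot signal was 191 (WT1), 225 (WT2) and 198 (WT3) in the WT channel and 157, 146 and 154 in the KO channel of the same arrays, over median local backgrounds of 42, 41.5 and 40 and of 37, 31.5 and 33. The ratios of 220668 autosomal probes were used, with a median spacing of 7.827 kb on the genome build mm8. Ratios are log2 of WT over KO, so a gain here is a higher WT than KO signal and a loss a lower one. The number of arrays limits the precision, and the labels do not say that the 3 WT DNAs came from separate animals.

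Whole chromosomes were compared to find changes of chromosome number. Chromosome 10 was lower in WT than in KO by 0.716-fold (log2 ratio -0.48 ± 0.0049, SD, n = 3), and chromosome 18 was 1.40-fold higher (0.48 ± 0.014). The other 17 autosomes had means between -0.018 and 0.053. The signals of the separate channels placed these differences in opposite DNAs. On chromosome 10 the KO signal lay 0.51 ± 0.0090 above the mean of the other autosomes, 1.43-fold, and the WT signal 0.013 ± 0.0019 above it. On chromosome 18 the WT signal lay 0.51 ± 0.011 above, 1.42-fold, and the KO signal 0.037 ± 0.0029. Of 705 genes tested on chromosome 18, 687 were higher in WT and 0 lower by the limma gene test described further on. Of 1232 on chromosome 10, 1154 were lower and 9 higher. Chromosome 18 holds Apc, the Wnt pathway tumour suppressor, at 0.49 ± 0.066, Nr3c1, the glucocorticoid receptor, at 0.49 ± 0.015, and Tcf4, an E-protein transcription factor, at 0.45 ± 0.0022. Chromosome 10 holds the cell cycle kinase gene Cdk4 at -0.58 ± 0.10, Mdm2, whose product marks the tumour suppressor Trp53 for breakdown, at -0.40 ± 0.043, and Tnfaip3, an inhibitor of NF-kB signalling, at -0.27 ± 0.048. The end of chromosome 5, from 123371738 to 152002764 (3195 probes), read 0.22 ± 0.036, a region chosen after its values were seen. The X chromosome read -0.0096 ± 0.0019 and the Y chromosome, with 592 probes, 0.23 ± 0.049. The exact sign-flip permutation test gave a two-sided p of 0.25 for each chromosome, the smallest that 3 arrays allow. With normexp background correction chromosome 10 read -0.29 ± 0.19, X 0.031 and Y -0.21, so the sign of X and Y was not stable.

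**Figure D1:**
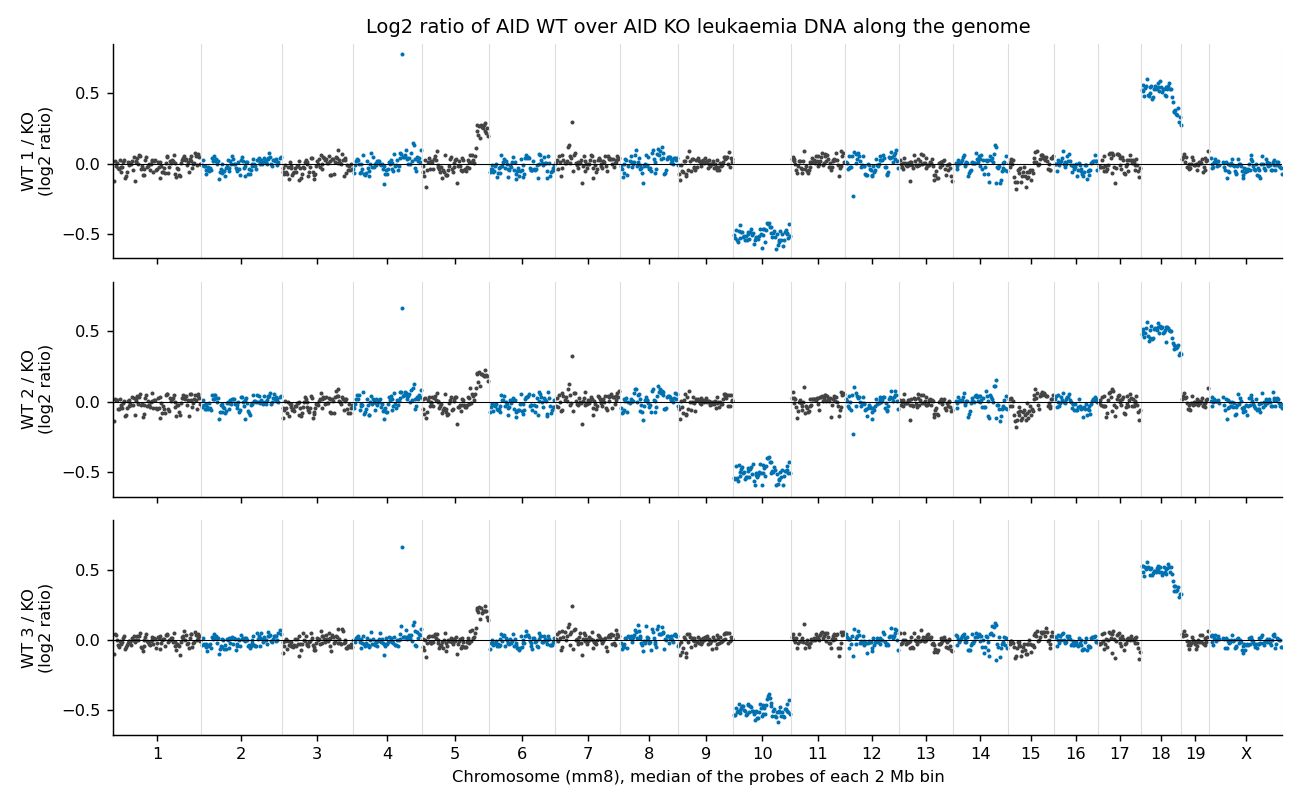
Log2 ratio of WT over KO along the genome for the 3 arrays, each point the median of the probes of a 2 Mb bin. Chromosome 10 lies near -0.48 and chromosome 18 near 0.48 on every array, and distal chromosome 5 lies above 0.

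**Figure D2:**
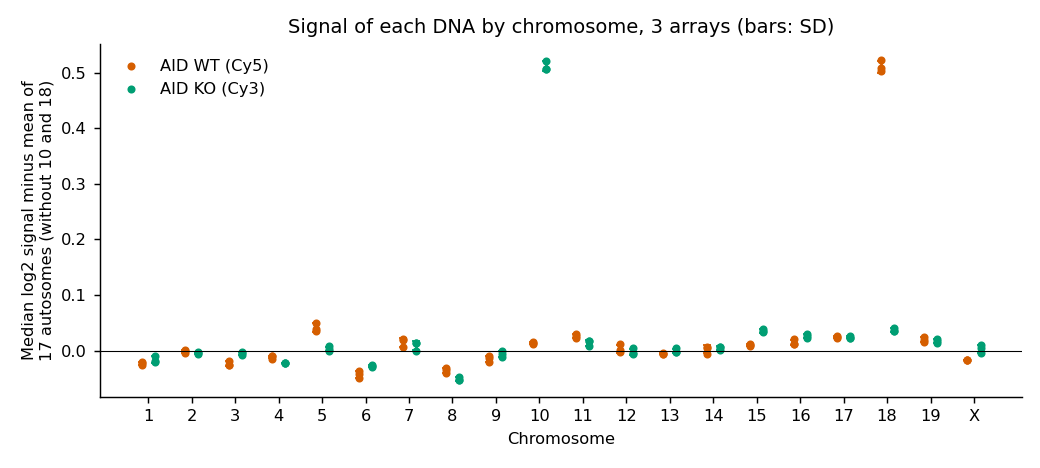
Median log2 signal of each chromosome in the WT (orange) and KO (green) DNA, minus the mean over 17 autosomes; points are the 3 arrays and the SD bars are about the size of the points or smaller. The KO signal of chromosome 10 and the WT signal of chromosome 18 both lie 0.51 above the other autosomes.

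Smaller regions were compared by segmentation, since the series describes its aim as AID-specific amplifications and deletions. The 3 arrays had 56, 61 and 51 called segments, 41, 43 and 36 of them gained and 15, 18 and 15 lost. They held 9.19%, 9.19% and 9.18% of the autosomal probes, most of them on chromosomes 10 and 18. On all 3 arrays together, 23 gained and 13 lost segments were called alike, and 32 of these 36 were shorter than 5 Mb, together 8877 kb. Of those 32, 10 lay within the immunoglobulin heavy chain locus. The calls covered 20204 shared probes, against a median of 0 and a highest of 19453 after 10000 circular shifts of the segments along the autosomes (permutation p = 0.0001, the smallest these shifts can give). Without chromosomes 10 and 18, an alternative chosen after seeing the data, 556 probes were shared and the highest shift gave 12 (permutation p = 0.0001). The shifts test chance placement only: the ratios share the KO DNA and the order of the dyes, so a change of the KO DNA is called on every array by construction.

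The longest shared gain under 5 Mb held the Skint genes, a family that shapes T cells of the skin. It ran from 111579573 to 113736936 on chromosome 4 (121 probes) and was 4.10-fold higher in WT (log2 ratio 2.04 ± 0.18, SD, n = 3). Both DNAs were dim there: among windows of as many probes the WT signal lay at percentiles 0.070 to 0.102 and the KO signal at 0.00046 to 0.00092. Skint3 read 3.06 ± 0.38, Skint4 2.70 ± 0.30, Skint9 2.62 ± 0.38, Skint11 1.40 ± 0.053 and Skint2 1.26 ± 0.077, and with normexp background correction all stayed positive but only Skint11 kept its call. The highest shared gain was a segment of 5 probes from 116564047 to 116580851 on chromosome 11, at the cDNA AK155119, with 4.23 ± 0.13. A segment on chromosome 4 from 138139095 to 138170226 read 3.99 ± 0.36 and held Pla2g2e, a secreted phospholipase gene (4.06 ± 0.60), and the cDNAs AK016969 (3.98 ± 0.24) and AK148187 (2.88 ± 0.60). The cDNA AK014098 (1.25 ± 0.13) reached into it. A segment of 15 probes inside Nrxn3, a neurexin gene on chromosome 12, read 3.54 ± 0.28 while the mean over all 183 probes of the gene was 0.29 ± 0.028. The other of the 5 highest were at the cDNAs BC040066 on chromosome 4 (3.30 ± 0.21) and M92417 on chromosome 16 (3.27 ± 0.28). Cwc22, a splicing factor gene on chromosome 2, lay in a segment with 2.65 ± 0.082. A segment on chromosome 15 read 2.62 ± 0.19, but the 1 probe of Apol7c in it read 0.41 ± 0.059. Some KO probes were not well above background, 2 in the Skint segment and 1 each in the segments with Pla2g2e and Apol7c, so these means and their ranks are approximate.

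By segment mean, the lowest shared loss was a segment of 5 probes within Rims2, a gene of the presynaptic active zone, from 39114743 to 39145111 on chromosome 15, with -2.29 ± 0.14 (SD, n = 3); 1 of these was not well above background in the WT DNA. Over all 58 probes Rims2 read -0.44 ± 0.022. The next were at BC110565 on chromosome 5 (-1.95 ± 0.18), within the heavy chain locus (28 probes, -1.94 ± 0.16, with a deeper run inside it given further on), at 1600014C10Rik on chromosome 7 (-1.75 ± 0.032) and again within the heavy chain locus at BC018322 (-1.54 ± 0.077). The segment on chromosome 7 also overlapped AK181724, which read -0.12 ± 0.031 over its 20 probes and reached into a neighbouring shared gain of 0.54 ± 0.051. A loss of 474 kb on chromosome 17 (66 probes, -0.57 ± 0.019) held Glo1, the glyoxalase gene, which lies in a segment known to be duplicated in some inbred mouse strains. There the WT and the KO signal both lay above the 99.9th percentile of windows of as many probes, and the KO signal was the higher. Of the 22 gained segments under 5 Mb, 16 had a KO signal under the 1st percentile of such windows on every array, and 4 had a WT signal over the 99th. Of the 10 lost ones, 3 had a WT signal under the 1st percentile and 6 a KO signal over the 99th. Under normexp background correction the shared segments fell to 2, where WT1, WT2 and WT3 had 20, 17 and 3 called segments and WT3 had 0 lost ones. With a segmentation penalty of 20 in place of 10, 19 shared segments were left.

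**Figure D3:**
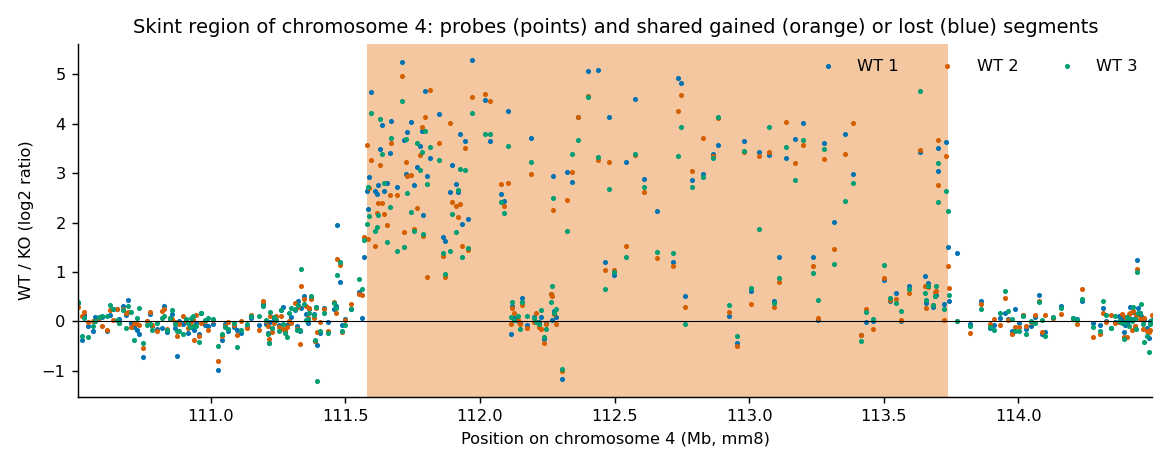
Log2 ratio of WT over KO of single probes around the Skint genes on chromosome 4 (mm8, Mb), with 1 colour per array and the shared gained segment shaded orange. Inside the segment the probes of all 3 arrays average 2.04, and probes near 0 stand among them.

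Changes of single WT samples were sought in the differences between arrays, in which the KO DNA cancels. The search covered the autosomes. A segment counted where the difference was 0.3 or more and the array itself was called in the same direction. By this rule there were 4, all on the WT1 array, and each lay in a region that was also called on the other arrays. The WT1 array also read furthest from 0 over the whole Skint segment (2.24, 1.97 and 1.90 in WT1, WT2 and WT3). The heavy chain loss of 28 probes did the same (-2.12, -1.86 and -1.83), but the chromosome 17 loss did not (-0.56, -0.59 and -0.55). A difference in ratio scale between the arrays was not tested and cannot be told apart from changes of single WT DNAs here. On chromosome 4, the segment from 111589916 to 111970732 with Skint4, Skint3 and Skint9 read 0.60 higher in WT1 than in the mean of the others, and the segment from 112400294 to 112762286 read 0.76 higher. On chromosome 12, the heavy chain segment from 113923075 to 114022833 at AK136471 read -0.59 and the segment at BC031703, from 115487265 to 115534700, read 0.90. Some probes were not well above background: 1 KO probe from 112400294 to 112762286, 2 WT probes at AK136471 and 1 KO probe at BC031703. These differences are therefore approximate. With probes well above background only, 3 segments were called in the differences. On the WT3 array 3 segments differed against the direction of their own call, so the rule left them out: -0.58 within Nrxn3 from 90133658 to 90209327, 0.51 in the heavy chain locus from 113928567 to 114005202 and -0.30 on chromosome 4 from 111655957 to 112826968. No autosomal segment that met the rule lay outside the calls of the other arrays. Segments called on the arrays themselves were not counted this way. Without chromosomes 10 and 18 these held 619, 624 and 600 probes on the WT1, WT2 and WT3 arrays, of which 556 were shared. On chromosome Y, which was not counted, the differences reached -0.56 and 0.39 on the WT1 array and -0.69 and 0.49 on the WT2 array. These were segments of 5 to 10 probes. Not well above background were 1 KO and 1 WT probe of the segment at -0.69 and 1 KO probe of that at 0.39, against 0 in those at -0.56 and 0.49. With plain background subtraction, an alternative chosen after seeing the data, 10 segments were called in the differences, 2 of them on 1 array alone.

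Antigen receptor loci were compared because B-lineage cells rearrange their immunoglobulin genes. Within the heavy chain locus (Igh, chromosome 12, 113703619 to 116641388, 291 probes), 6 gained and 4 lost segments were called on all 3 arrays. The deepest loss was a run of 15 probes from 113923075 to 114042869 with the same outermost probes on every array. It read -3.54, -3.03 and -3.05, and 2 of its probes were not well above background in the WT DNA. There the WT signal was at or under the 0.000455th percentile of windows of as many probes, and the KO signal between the 35.6th and the 53.6th. Over the longer shared segment of 28 probes that holds this run, the WT signal was also under the 1st percentile, but the KO signal lay at percentiles 99.6 to 99.7. Over the whole locus the mean was 0.12 ± 0.024 (SD, n = 3), since 99 probes lay in gains and 61 in losses. The kappa light chain locus (Igk, chromosome 6, 233 probes) read -0.10 ± 0.015. Its lowest window of 10 probes, from 70449742 to 70607100 on every array, read -0.62, -0.54 and -0.52. The lambda locus had 1 probe identified, with -0.22 ± 0.37. Among the T-cell receptor loci, alpha and delta read 0.11 ± 0.034 (90 probes), beta -0.031 ± 0.011 (88 probes) and gamma -0.23 ± 0.0071 (14 probes). The highest window of alpha and delta read 1.346, 0.97 and 1.01, but 0.60, 0.49 and 0.54 over probes well above background. No test was made of these values. Under normexp background correction Igh read 0.019, Igk -0.011 and beta 0.0014. The lowest Igh window of 10 probes lay inside the deep run without this correction, from 113928567 to 114005202, at -3.76, -3.31 and -3.03. With it the lowest window lay elsewhere and was less deep. It read -1.67 (WT1) and -1.47 (WT2) from 116045060 to 116132724, and -0.86 (WT3) from 116013173 to 116095131.

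**Figure D4:**
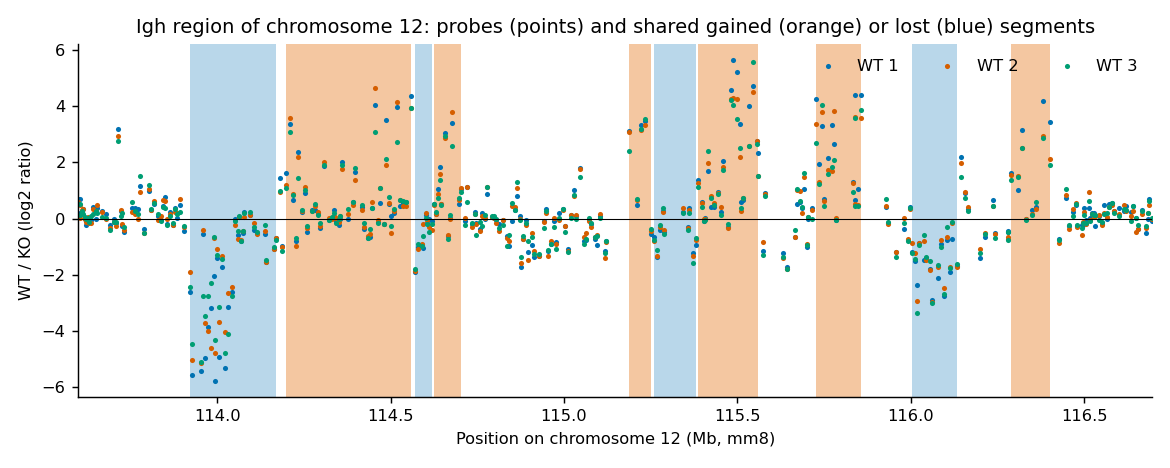
Log2 ratio of WT over KO of single probes across the heavy chain locus on chromosome 12 (mm8, Mb), with 1 colour per array and the shared gained (orange) and lost (blue) segments shaded. The first shaded loss holds the run of 15 probes that averaged -3.54, -3.03 and -3.05.

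Single genes were tested for a ratio different from 0. Of the genes fixed in advance for their part in B-lineage leukaemia and reported here, only Cdkn2a, a cell cycle inhibitor gene often deleted in such leukaemias, passed, and it was slightly higher in WT (0.16 ± 0.0090, SD, n = 3, 1.12-fold, limma and Benjamini-Hochberg adjusted p = 0.00730). The B-lineage transcription factor genes Pax5 (-0.060 ± 0.013, adjusted p = 0.110), Ebf1 (0.022 ± 0.033, adjusted p = 0.538) and Ikzf1 (0.026 ± 0.040, adjusted p = 0.487) did not pass. Neither did Myc, on 1 probe (-0.030 ± 0.19, adjusted p = 0.761), nor Abl1, the kinase gene of the fusion (0.079 ± 0.037, adjusted p = 0.0788). With other settings Cdkn2a lost its call (normexp background correction, 0.28), while Abl1 passed with the median of its probes (0.17) and among genes with at least 3 probes (0.079), Pax5 among genes with at least 3 probes (-0.060) and Myc without WT3 (-0.14). Bcr had no value of its own. Across the autosomes 6851 of 24636 genes were higher in WT and 4423 lower, 45.8% together, at a median size of 0.22, and 3750 of them differed by 0.3 or more. Outside called segments 9374 of 22646 genes passed. Among single probes, 53885 of 220624 were higher and 53697 lower, but 36910 were higher and 17996 lower with normexp background correction.

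The largest changes outside called segments were at genes with few probes. Higher in WT were 4930515G01Rik (3.72 ± 0.038, SD, n = 3), the olfactory receptor gene Olfr1124 (3.55 ± 0.84) and Rgs9bp, a retinal anchor protein gene (3.44 ± 0.33), each with 1 probe and each negative with normexp background correction. Lower were Hbq1a, a globin gene (-2.04 ± 0.17), Olfr209 (-2.02 ± 0.13), Ccne2, a cyclin E gene (-1.19 ± 0.083), and Rexo4 (-1.10 ± 0.047). The remaining 6 of the 10 lowest and the remaining 7 of the 10 highest lay at cDNAs or in the segments above. The test leaves out the spread between KO leukaemias, as there was 1 KO DNA, and WT was always in Cy5, so a dye difference of a probe and a difference between the DNAs give the same ratio. With normexp background correction 3036 genes passed, and without WT1 6554; of 67 named genes, 31 lost their call with normexp background correction and 6 changed sign.

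Gene lists fixed in advance were compared with all other genes, and none of those reported shifted as a set (limma camera, adjusted over 9 lists, 1 of them not reported here). Of genes reported as AID off-targets in B cells, 10 of 24 were higher in WT and 0 lower (10 and 0 adjusted over the list alone), with adjusted p = 0.482. The largest was Cd74, the invariant chain of the class II antigens, which read 2.00 ± 0.052 (SD, n = 3) over 2 probes on chromosome 18. The shared gain of chromosome 18 read 0.48, so the excess of Cd74 rests on these 2 probes. It was followed by Btg2 (0.51 ± 0.28, 1 probe), Il21r (0.51 ± 0.10, 4 probes) and the histone gene H2ax (0.33 ± 0.16, 1 probe). Btg2 did not pass without WT2 (0.51), nor H2ax without WT1 (0.31) or without WT2 (0.27). Genes of T and myeloid lineages had 10 of 18 higher and 1 lower (10 and 1 over the list alone, adjusted p = 0.482). They included Mpo, myeloperoxidase (1.07 ± 0.32), Csf1r, a macrophage growth factor receptor gene within the chromosome 18 gain (0.91 ± 0.056), and Cebpe (0.43 ± 0.045). The list also held Klf1 (0.42 ± 0.17), a gene of the red cell lineage. Among B-lymphoid genes 7 of 32 were higher and 2 lower (7 and 1 over the list alone, adjusted p = 0.882), with Btla, an inhibitory receptor (0.60 ± 0.061), and Spi1 (0.41 ± 0.092) beside the chromosome 18 genes Nr3c1 and Tcf4. Btla turned to -0.019 with normexp background correction.

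Among tumour suppressors 9 of 35 were higher and 5 lower (9 and 5 adjusted over the list alone, adjusted p = 0.713). These included Pmaip1, a pro-apoptotic gene on chromosome 18 (0.58 ± 0.056, SD, n = 3), and Dok2 (0.37 ± 0.039). Among oncogenes and cell cycle genes 10 of 37 were higher and 2 lower (9 and 2 over the list alone, adjusted p = 0.713), with the Myc family genes Mycl (0.60 ± 0.080) and Mycn (0.26 ± 0.12). DNA repair and mutation genes had 7 of 23 higher and 2 lower (6 and 2 over the list alone, adjusted p = 0.651). They included Apobec2 (0.42 ± 0.015), Apobec3 (0.22 ± 0.034) and Apobec1 (-0.18 ± 0.088), which did not pass without WT1 (-0.19).

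Olfactory and vomeronasal receptors, a large family with no known role here, had 184 of 693 higher and 169 lower (187 and 177 adjusted over the list alone, adjusted p = 0.512). Their mean was -0.0057 and their median 0.0020, so these differ in sign. The largest beside Olfr1124 and Olfr209 were Olfr1402 (0.99 ± 0.078, SD, n = 3) and Olfr307 (0.76 ± 0.33). Gene families that vary in copy number between mouse strains had 15 of 42 higher and 10 lower (16 and 11 over the list alone, adjusted p = 0.846). With an estimated correlation between genes the adjusted p of the lists lay between 0.664 and 0.925. The heavy chain list held only Ighmbp2, a helicase gene on chromosome 19 (0.20 ± 0.088), the alpha and delta list only Trav13-5 (-0.19 ± 0.089) and the list of construct homologues only Abl1, and the other receptor lists matched no gene, so these were not tested as sets. Ighmbp2 did not pass without WT1 (0.19) or without WT3 (0.16), nor Trav13-5 without WT1 (-0.14) or without WT2 (-0.21).

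The ratios of the 3 arrays were compared with each other, since they share the KO DNA. Across 220624 autosomal probes, which are not independent replicates, Pearson's r was 0.895 (WT1 and WT2), 0.873 (WT1 and WT3) and 0.855 (WT2 and WT3), and Spearman's rho 0.836, 0.798 and 0.764. Simulated unchanged WT samples that shared the KO DNA gave r of 0.50, 0.50 and 0.50. Ratios that share their reference, with equal noise in both DNAs, take this value by arithmetic, so it was fixed in advance. The covariance was 0.111, 0.107 and 0.0987, against 0.0582, 0.0573 and 0.0565 in the simulation. Outside called segments the mean r was 0.827, against simulated values of 0.496, 0.501 and 0.503.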

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

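Both tests of the gene calls outside called segments were chosen after the result was seen. So were the tests of one clone and of strain among the shared segments. The tests of the heavy chain signals and of chromosomes 10 and 18 were written before their results. For a KO loss of chromosome 18 the written bound was not met, and the reading used below in its place was not part of it.

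The mitochondrial probes, which no comparison used, stood out: 2 probes on the mitochondrial chromosome averaged 0.92 ± 0.082 (SD, n = 3), with 1.01, 0.92 and 0.85 on the 3 arrays, above the level of 0 at which WT and KO would be equal.

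Chromosomes 10 and 18 differed between WT and KO, and the ratio does not say in which DNA. A loss of chromosome 10 in the WT DNA needs a WT signal below the other 17 autosomes, and it lay 0.557 of their SDs above them. A loss of chromosome 18 in the KO DNA needs a KO signal below them, and it lay 1.70 SDs above; the bound set in advance was within 1 SD, but a signal on the opposite side speaks against a loss as well. What remains is a gain of chromosome 10 in the KO DNA, whose signal lay 23.5 SDs above the other autosomes, and a gain of chromosome 18 in the WT DNA, at 21.9 SDs. Both may be an extra chromosome in most cells of the leukaemia, and neither can be tied to AID with 1 KO DNA.

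The deep heavy chain loss and most other segments were alike on the 3 WT arrays. More copies in the shared KO DNA at the heavy chain loss would leave the WT signal ordinary, but the WT signal lay at or under the 0.000455th percentile on every array, so over these 15 probes the values argue against it, while over the shared segment of 28 probes around them the KO signal was high too, at percentiles 99.6 to 99.7. That the WT DNAs come from one clone or one sample remains open. In the differences between arrays, 0 autosomal segments that met the rule lay outside the calls of the other arrays. The heavy chain loss had the same outermost probes on each array. So did the end of chromosome 5, a region chosen after its values were seen. Its WT signal lay 0.25 ± 0.020 above the mean of the 17 autosomes other than 10 and 18, its KO signal 0.035 ± 0.0044. Plain background subtraction, however, gave 2 segments outside the calls of the other arrays. On chromosome Y the arrays differed by up to -0.69 over 5 probes, but 1 KO and 1 WT probe there were not well above background. A strain difference between the mice also remains open, for the heavy chain loss as for the other segments: 3 shared segments under 5 Mb held members of strain-variable families, against a median of 0 and a highest of 3 in 10000 random placements (permutation p = 0.0002). An effect of AID on these segments was not tested, as the design gives no second KO leukaemia. Rearrangement of the immunoglobulin genes, for which the heavy chain locus was compared, was not tested as a cause of its segments either.

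Outside called segments 9374 genes passed the test. Copy number differences that span neighbouring probes but lie under the call threshold would make these probes share their ratio. Their correlation was 0.0684, 0.083 of that of the same probe between arrays, which argues against such differences as the general cause. Differences that cover single probes could not show this way. Longer ones past the threshold had been removed with the called segments, so the test does not cover them. A response of the single probe to the dyes may contribute: the same probe correlated at 0.827 between arrays, but arrays that share the KO DNA gave 0.496 to 0.503 in simulations without change. That simulated level follows from the shared reference with equal noise in both DNAs, so the comparison decides nothing. With WT always in Cy5, a dye response and sequence differences under single probes therefore cannot be told apart.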

How the results depend on the processing

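The alternatives with plain background subtraction and the count of shared segments without chromosomes 10 and 18 were chosen after the result was seen; the others were planned. No pairing beyond the ratios was possible, because each ratio already pairs a WT DNA with the KO DNA on its array. Of 634 alternative values for 67 named genes, 568 kept direction and side of the threshold, 50 lost the call, 4 gained one and 12 changed sign; of 202 for 24 other results, 171 were the same, 27 moved and 4 changed sign.

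Normexp background correction changed most. It gave 3036 genes and 54906 probes past the test, 13.3 called segments per array with 7.23% of probes, 2 shared segments and 0 in the differences between arrays. The mean correlation was 0.704. Igh read 0.019, Igk -0.011, T-cell receptor beta 0.0014 and gamma -0.14, X 0.031, Y -0.21 and the strain-variable families 0.0023. 4930515G01Rik (-0.16), AK136471 (0.021), Btla (-0.019), Olfr1124 (-0.19), Pax5 (0.020) and Rgs9bp (-0.13) changed sign. It adds an offset of 50 to the background-corrected signals, which shrinks ratios of dim spots, and it left a trend with brightness: on the WT3 array the median ratio ran from -0.40 in the dimmest to 0.78 in the brightest eighth of probes, against -0.045 to 0.091 without it.

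Plain background subtraction gave a share of 9.178%, 10 segments in the differences, a gamma mean of -0.202, a correlation of 0.853 and Myc at 0.0054. Loess gave a share of 9.195%, beta -0.017, gamma -0.216 and Myc 0.025. Probes well above background gave a share of 9.145%, Igh 0.097 and AK136471 0.042. A threshold of 0.5 gave a share of 3.74%, a penalty of 20 gave 28.7 segments per array, 19 shared and 9.09%, and segments of at least 10 probes 9.1996%. Requiring at least 3 probes left fewer genes to test and 6789 passed. The median of the probes gave AK181724 0.022. Probes in no called segment correlated at 0.827. Leaving out each array gave 6554 to 9446 genes (6554 without WT1) and Myc between -0.14 and 0.027; AK136471 (-0.098 to -0.079) and AK181724 (-0.13 to -0.10) lost their calls without any 1 array. Except where the construction is named, the cause was not tested.

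Not run were the series table, whose scale, centring and direction are not stated and whose numbers do not follow the features; the slide as a block, with 1 array per slide; and probe GC content, with no probe sequences or genome of the build at hand. At most 373 of 238202 features per channel and array were not well above background. By that measure few probes were limited, 2 of them in the WT signal of the deep heavy chain loss. It does not cover dim signals that passed it. Of the 22 shared gained segments under 5 Mb, 16 had a KO signal under the 1st percentile of windows of as many probes on every array.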

Other observations

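The values of the regions named here were looked up after the result was seen. The end of chromosome 5, from 123371738 to 152002764 with 448 named features, read higher in WT on all 3 arrays, with 0.26, 0.19 and 0.21, below the threshold for a call. The same first and last probe bounded this segment of 3195 probes on every array. Its WT signal lay 0.25 ± 0.020 (SD, n = 3) above the mean of the 17 autosomes other than 10 and 18, higher than all 93 stretches of as many probes taken from autosomes other than 5, 10 and 18, and its KO signal 0.035 ± 0.0044. The end of chromosome 18, from 73393368 to 90727455, had a WT signal 0.42 ± 0.019 above the same 17 autosomes, against 0.53 ± 0.017 for the chromosome up to 70909050. Its KO signal was the higher of the same parts, 0.076 ± 0.0039 against 0.024 ± 0.0030, so the step in the ratio is not from the WT signal alone. A stretch of chromosome 10 from 74609785 to 85574404 read -0.40 and -0.41 on the WT2 and WT3 arrays, less deep than the segments on either side at -0.50 to -0.51 in WT2.

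Among 200292 probes outside called segments, 863 had a mean log2 ratio above 1 and 424 below -1. Beyond the immediate neighbour the correlation of the mean ratio between probes fell to 0.047 at 10 probes apart and 0.036 at 50.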
